A study of Homo sapiens with 6 samples.

How the data were processed

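RNA from A375 melanoma cells was compared between 3 vehicle arrays (0.1% DMSO) and 3 arrays of cells given 10 µM vemurafenib for 24 h. Per the labels' protocols, 1000000 cells were seeded in each 10 cm dish and grown for 24 h before treatment, and 250 ng of total RNA was labelled with biotin for single-colour Affymetrix arrays. Per the series' design text, the replicates came from separate stocks of cells handled on separate days, so within a group they are independent replicates of culture. That text also pairs vehicle and drug dishes within lettered batches. The main test left this pairing out, because the labels do not show which arrays form the pairs.

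The deposited values are log2 levels per probe set, and RMA and Partek are named, without versions, per the submitters' processing notes. RMA as usually run subtracts background, quantile normalizes the arrays and summarizes the probes of a set, which compresses large folds and would hide a change of total RNA per cell. The summarization level, the handling of batches and a genome build are not given in the sources used here, so no coordinates are printed. The table held 33297 probe sets and 6 arrays, with 0 missing values and 0 columns of other samples. Its values ran from 2.67 to 14.56, array medians from 7.69 to 7.73, lower quartiles from 6.04 to 6.13 and upper quartiles from 9.54 to 9.62, and the largest difference between arrays at the same rank was 0.17. No detection calls were used here, and the number of arrays limits the precision.

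Probe sets were named through the platform annotation of 2016: 19460 carried 1 gene symbol, 1754 carried several and 12083 had no gene in that table. By Entrez identifier, 19429 probe sets with 1 symbol matched a current gene table, and 0 symbols needed an update. The symbols supplied for these were thus already current ones, whatever the date of the annotation. Where a gene had more than 1 probe set (769 genes), the set with the highest mean over the 6 arrays was kept, which left 18417 genes. There was no filter on dim probe sets.

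Groups were taken from the sample labels. The test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes at default settings on the deposited log2 values, the group as the only term, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The prior degrees of freedom were 7.08. Folds are 2 to the power of the absolute log2 change. Intervals have a confidence level of 95%. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 36 lists, with an estimated correlation and with fry as alternatives. Lists under 5 measured genes were to be left out, and all 36 were tested. Members that passed were counted over all genes tested and again adjusted over the list alone. The lists covered signalling, cell cycle, metabolism, melanoma cell state, cell death, stress, immune and matrix genes, markers of keratinocytes, fibroblasts, endothelial cells and leukocytes, and reference genes.

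Genes were named by a rule: the 15 largest rises and 15 largest falls among genes past the threshold that moved the same way in each same-numbered vehicle and vemurafenib array, up to 4 members of each list by size of change among those past the threshold, any member of a list of 8 or fewer measured genes where wanted, and 18 genes fixed in advance. Of those 18, 16 are reported here and the remainder are not analysed here. The design, lists, naming rule and all alternatives except the joint omission of the farthest array of each group were fixed before the data were examined.

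The alternatives were the replicate number as a fixed or random block (statmod 1.5.0), centring on array medians, renewed quantile normalization, omission of the dimmest 25% or 50% of genes, the mean of a gene's probe sets, a test of every probe set, an intensity trend with robust eBayes, array weights, a threshold of 0.01 and omission of each array in turn. The omitted-array fits pooled the spread over both groups.

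The scripts were tested on simulated data with the real genes' means. Of 50 genes changed at each size, limma recovered 2% at a log2 change of 0.25, 62% at 0.5, 92% at 1 and 100% at 2, with 7 false calls among unchanged genes of the 18417. Camera called 9 of 9 lists shifted by 0.3 and 0 of 20 untouched lists, with preset and with estimated correlation. The simulated noise was independent between genes, so this says nothing about correlated genes. Few genes were changed in the simulation, whereas 45.5% passed in the real data. The simulated adjustment was therefore stricter, and these recovery rates do not describe the real comparison. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.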

Results

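A375 is an established human melanoma cell line. Its RNA was profiled on single-colour Affymetrix arrays after 24 h in vehicle (0.1% DMSO) or in 10 µM vemurafenib, a kinase inhibitor used to treat melanoma. Each group held 3 arrays, prepared from separate stocks of cells on separate days. The design text pairs vehicle and drug dishes, a pairing that the main test did not use. The deposited values were log2 levels per probe set, from 2.67 to 14.56, and the array medians lay between 7.69 and 7.73. Arrays carry no read depth, so the number of arrays limited the precision. The comparison asked which genes and gene groups differed between drug and vehicle, and 18417 genes were tested with limma. Every level is a mean of log2 values with its SD over 3 arrays, and every change is vemurafenib minus vehicle on the log2 scale.

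With vemurafenib, 24 of 26 genes switched on by the ERK kinase pathway fell, among them the 5 largest falls of single genes (DUSP6, ETV5, ETV4, SPRY2 and SPRY4), and all 37 measured genes of DNA replication and S phase fell. DUSP6, a phosphatase that switches ERK off (probe set 7965335), went from 11.21 ± 0.04 to 7.0 ± 0.03 (SD, n = 3), which was 18.5-fold lower, with a log2 change of -4.21 (SE 0.07). CD36, a cell surface receptor that takes up fatty acids (probe set 8133876), went from 4.48 ± 0.07 to 10.26 ± 0.05 (SD, n = 3), a log2 change of 5.78 (SE 0.07) or 55.0-fold between array values. Its vehicle level lay below 5.50, the median of olfactory receptor genes, which melanoma cells hardly express, so the fold is limited by background and is not an exact ratio of RNA. The limma adjusted p after Benjamini-Hochberg adjustment was 1.65e-11 for DUSP6 and 2.21e-12 for CD36.

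Of the 18417 genes, 8371 (45.5%) passed an adjusted p threshold of 0.05 in limma with Benjamini-Hochberg adjustment, 4281 of them higher and 4090 lower with vemurafenib. When each array was first centred on its median, the split was 3682 higher and 5630 lower. Changes of at least 2-fold were seen for 1048 genes (566 higher, 482 lower) and of at least 4-fold for 132 genes (83 higher, 49 lower). The 2-fold balance turned to 488 higher and 542 lower after centring, and to 335 higher and 390 lower without the dimmer 50% of genes. Most of the genes that passed changed little: 5472 of them differed by under 1.5-fold. The 3 vemurafenib arrays lay wholly above or wholly below the 3 vehicle arrays for 10200 genes (55.4%), where chance alone gives 10%. Among the 163 genes named by rule that passed the threshold, 162 had groups that lay apart in this way, the exception being RPS24. For 29 of these 163, at least 1 group mean lay within the range of the dimmest 25% of genes (up to 6.87) and was not shown to be above background. In vehicle alone these were ANGPTL7, CD24, CD36, CRYAB, DCN, ESRRG, FAP, FGFR2, IFI44L, IFIT2, LINC00518, PPARGC1A, PRUNE2 and TMEM45A. With vemurafenib alone they were ADGRF1, CEMIP, CLSPN, CXCL8, ETV5, FAM111B, LIF, MMP1, MRGPRX4, NRCAM, NT5E, SPRY4 and STC2. CD14 and PECAM1 were dim in both groups. Folds of these genes are ratios of array values that background limits.

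**Figure D1:**
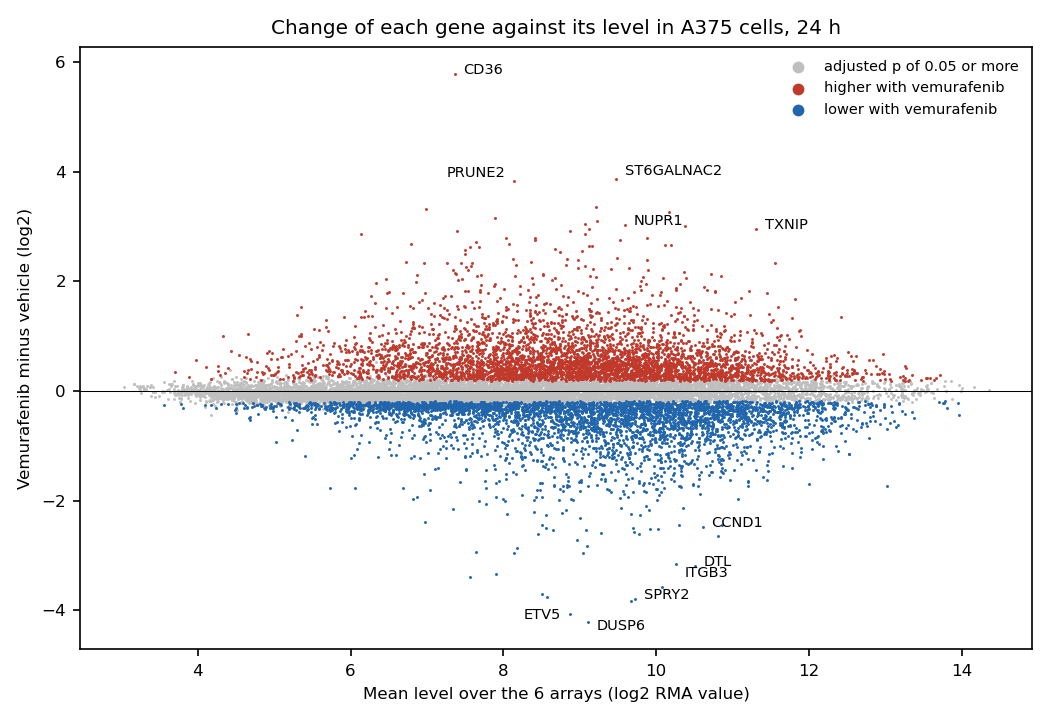
Each point is a gene, with its mean log2 level over the 6 arrays on the x axis and its log2 change (vemurafenib minus vehicle) on the y axis, coloured by direction where it passed the adjusted p threshold of 0.05. CD36 stands highest at 5.78 and DUSP6 lowest at -4.21.

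After CD36, the largest rises were those of ST6GALNAC2, a sialyltransferase (log2 change 3.88, SE 0.09, 14.7-fold), and PRUNE2 (3.84, SE 0.14, from a dim vehicle level of 6.22). TCN1, a vitamin B12 binding protein, rose by 3.36, and CD24, a surface sialoglycoprotein whose vehicle level of 5.32 also lay below that median, by 3.32. MOXD1, ANGPTL7, SERPINF1, ZNF536, NUPR1 and MGP rose by 3.26 to 3.01, and CYP1B1, TXNIP, TRPM3 and the noncoding RNA LINC00518 by 2.95 to 2.91. On the other side, DUSP6 was followed by the ETS transcription factors ETV5 (-4.08, SE 0.09, 16.9-fold lower) and ETV4 (-3.84, SE 0.08, 14.3-fold lower). SPRY2 and SPRY4, feedback inhibitors of receptor signalling, changed by -3.80 and -3.75. FAM111B changed by -3.71, FST, which encodes the activin antagonist follistatin, by -3.59, ADGRF1 by -3.40 and CEMIP, a hyaluronan-degrading protein, by -3.34. The replication genes DTL (-3.19) and CLSPN (-2.97), the integrin subunit ITGB3 (-3.16), LRATD2 (-2.96), MRGPRX4 (-2.94) and NT5E (-2.86) completed the 15 largest falls.

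Gene groups were compared through 36 lists, of which 19 passed limma's camera at its preset correlation of 0.01 with Benjamini-Hochberg adjustment, 7 shifted up and 12 down. With the correlation estimated from the arrays, camera passed 0 lists, the lowest adjusted p being 0.325, and 3 lists had an unadjusted p under 0.05. The self-contained test fry passed 27 lists (12 up, 15 down). It asks whether the genes of a list move, on balance, in 1 direction and makes no comparison with other genes. Of the lists that passed camera 18 also passed fry, and oxidative phosphorylation did not. Another 9 passed fry but not camera, with limma adjusted p values of 0.000150 to 0.0352: glycolysis, regulators of glycolysis, TCA cycle, pigment cell differentiation, dedifferentiated melanoma markers, integrated stress response, p53 targets, extracellular matrix and invasion, and endothelial markers. For a member named because it moved against its list, the choice was made after its values were seen. Some lists share members, so they are not independent. For example, LIF, CXCL8, BYSL, MYC and EPHA2 are in ERK pathway output and also in another list.

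Of 26 genes of ERK pathway output, 24 fell and 1 rose, over all genes tested and likewise when adjusted over the list alone. The exception was FOS, an immediate early transcription factor, at 0.56. Besides DUSP6, ETV5, ETV4 and SPRY2, the list held CCND1, the cyclin D1 gene that drives entry into the cell cycle, which went from 11.86 ± 0.05 to 9.37 ± 0.02 (SD, n = 3), 5.61-fold lower. MYC, a growth-promoting transcription factor, was 2.54-fold lower (-1.35, SE 0.09). The list passed camera in limma with an adjusted p of 6.53e-17, against adjusted p = 0.325 with an estimated correlation.

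All 37 measured genes of DNA replication and S phase fell, and all 36 of mitosis, with the same counts when adjusted over the list alone. The median log2 change was -1.52 for the replication list and -1.06 for the mitosis list. DTL fell 9.15-fold, CLSPN, a replication checkpoint protein, 7.82-fold, MCM10, a replication initiation factor, 7.09-fold and CCNE2, the cyclin E2 gene, 6.08-fold. Among mitotic genes the largest falls were those of the kinase CDK1 (3.28-fold), the kinetochore component NUF2 (2.93-fold), the spindle checkpoint kinase TTK (2.85-fold) and the kinesin KIF23 (2.84-fold). Camera in limma gave adjusted p values of 2.11e-25 and 9.35e-19. Both lists stood at adjusted p = 0.387 with an estimated correlation. Of 16 cell cycle inhibitors and quiescence genes, 9 rose and 1 fell (10 and 1 when adjusted over the list alone), with camera at 0.00573 in limma and adjusted p = 0.387 with an estimated correlation. HBP1, a transcriptional repressor, rose 2.93-fold, FOXO4 1.78-fold, BTG1 1.70-fold, RBL2, a retinoblastoma family member, 1.53-fold and the CDK inhibitor CDKN1B 1.28-fold, while CDKN2D changed by -0.31.

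**Figure D2:**
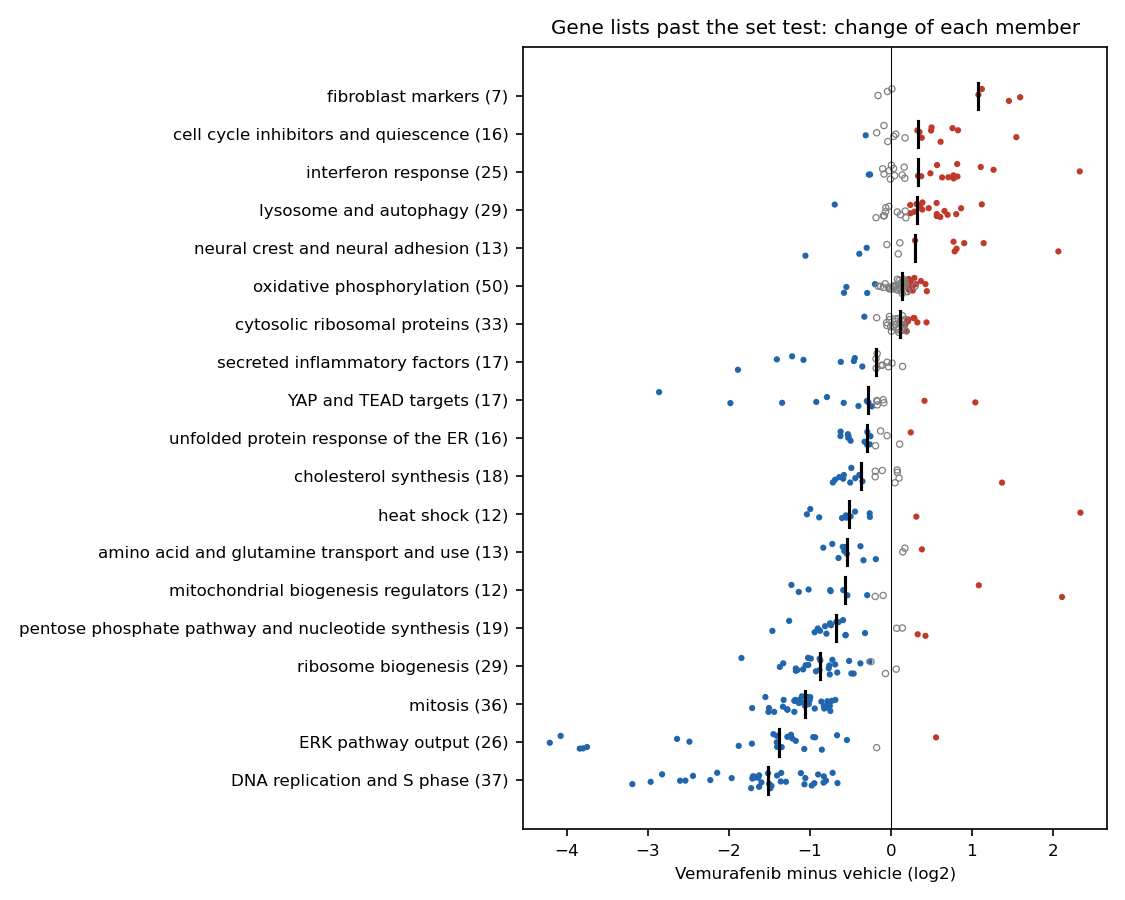
Log2 change (x axis, vemurafenib minus vehicle) of each measured member of the 19 lists that passed camera at its preset correlation, with the number of members in parentheses; filled points passed the adjusted p threshold of 0.05, open points did not, and black bars are list medians. The medians run from 1.08 for fibroblast markers to -1.52 for DNA replication and S phase.

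Of 29 ribosome biogenesis genes 26 fell and 0 rose (27 fell when adjusted over the list alone), with LYAR 3.59-fold lower, DKC1, the pseudouridine synthase, 2.59-fold, NOP16 2.51-fold and BYSL 2.26-fold. The list had a camera adjusted p of 1.12e-12 in limma and adjusted p = 0.387 with an estimated correlation. Of 33 cytosolic ribosomal protein genes, 9 rose and 1 fell (3 and 0 when adjusted over the list alone), with RPL10A at 0.44, RPS9 at 0.33 and RPL7A at 0.29. The fall of RPS24 (-0.33, limma adjusted p 0.0342) was lost in 7 of 17 alternatives, over which its adjusted p ran from 0.00303 to 0.136. Among these were the fits without vehicle replicate 1 (limma adjusted p 0.101), vehicle replicate 2 (0.0978), vemurafenib replicate 1 (0.0852) or vemurafenib replicate 2 (0.136). The ribosomal protein list passed camera at 0.0322, with adjusted p = 0.535 with an estimated correlation, and its call ended in 9 of 15 alternatives, among them centring (mean change 0.043 against 0.104). It also ended without vehicle replicate 3 (limma adjusted p 0.0850), vemurafenib replicate 1 (0.0501) or vemurafenib replicate 3 (0.0509). The adjusted p ran from 0.00581 to 0.101 over these alternatives.

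Glucose metabolism genes moved both ways. Of 21 glycolysis genes, 10 fell and 4 rose (11 and 4 when adjusted over the list alone), and the list did not pass camera in limma (adjusted p 0.107). Its median change was -0.18, and it passed fry (limma adjusted p 0.00174), which makes no comparison with other genes. HK2, the hexokinase that starts glycolysis in many tumours, was 2.45-fold lower (-1.29, SE 0.07), the glucose transporter genes SLC2A3 and SLC2A1 were 1.91-fold and 1.45-fold lower, PDK1, which restrains pyruvate dehydrogenase, 1.83-fold lower and LDHA, lactate dehydrogenase A, 1.34-fold lower. PFKFB2, which makes an activator of phosphofructokinase, was 1.79-fold higher, and ALDOC, PFKFB4 and PFKM also rose. Of 10 regulators of glycolysis, 5 rose and 2 fell, as when adjusted over the list alone, and the list missed the camera threshold in limma (adjusted p 0.0756). TXNIP, which limits glucose uptake, rose 7.72-fold from 9.84 ± 0.11 to 12.79 ± 0.07 (SD, n = 3). Its relative ARRDC4 rose 2.62-fold and MLXIP, a glucose-sensing transcription factor, 1.39-fold, whereas HIF1A, the hypoxia-inducible factor, stood at 12.54 ± 0.07 and 12.41 ± 0.08 (SD, n = 3; limma adjusted p 0.184). Of 18 HIF1 targets outside glycolysis 8 rose and 5 fell, as when adjusted over the list alone, among them EGLN3 (3.08-fold higher), TMEM45A (1.74-fold higher), ANGPTL4 (1.88-fold lower) and ERO1A (1.72-fold lower), and the list's camera adjusted p in limma was 0.469.

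Of 19 genes of the pentose phosphate pathway and nucleotide synthesis, 15 fell and 2 rose, also when adjusted over the list alone. CTPS1, the CTP synthase, fell 2.76-fold, the phosphoribosyl pyrophosphate synthetases PRPS2 and PRPS1 2.39-fold and 1.92-fold, and PAICS, a purine synthesis enzyme, 1.87-fold, against rises of IMPDH2 (0.43) and TALDO1 (0.33). Camera in limma gave an adjusted p of 6.16e-05, and adjusted p = 0.387 with an estimated correlation. Of 13 genes of amino acid and glutamine transport and use, 10 fell and 1 rose (10 and 2 when adjusted over the list alone), with the transporters SLC7A1, SLC1A5 and SLC38A1 at -0.83, -0.72 and -0.65 and ODC1, the first enzyme of polyamine synthesis, at -0.59. The riser was the glutamine synthetase gene GLUL (0.38), and the list passed camera in limma at 0.0110, with adjusted p = 0.411 with an estimated correlation.

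Among 12 regulators of mitochondrial biogenesis, 8 fell and 2 rose (9 and 2 when adjusted over the list alone). PPARGC1A, a coactivator that drives mitochondrial biogenesis, rose 4.33-fold from 6.64 ± 0.26 to 8.76 ± 0.32 (SD, n = 3), and the nuclear receptor gene ESRRG 2.12-fold, while the mitochondrial transcription factor gene TFB1M fell 2.34-fold and the coactivator gene PPRC1 2.20-fold. The list's camera adjusted p in limma was 0.0149, downward, with adjusted p = 0.453 with an estimated correlation. Of 50 oxidative phosphorylation genes, 14 rose and 4 fell (11 and 3 when adjusted over the list alone), all by small amounts, such as NDUFB5 (0.45), COX7C (0.43), CYCS (-0.58) and NDUFAB1 (-0.55). Their camera adjusted p in limma was 0.0321, with adjusted p = 0.666 with an estimated correlation. The list did not pass fry (limma adjusted p 0.0682). Its camera call ended in 7 of 15 alternatives, including centring (mean change 0.035 against 0.096) and leaving out vehicle replicate 2 (limma adjusted p 0.0967) or vemurafenib replicate 3 (0.0740), within a range of 0.00635 to 0.170. Of 20 TCA cycle genes 4 rose and 2 fell, likewise when adjusted over the list alone, with ACO1 at 0.63, PC at 0.61, IDH2 at 0.41 and IDH3A at -0.51, and a limma camera adjusted p of 0.178. That list passed fry (limma adjusted p 0.0352) and, after renewed quantile normalization, camera (0.0301, range over the camera alternatives 0.0301 to 0.354).

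**Figure D3:**
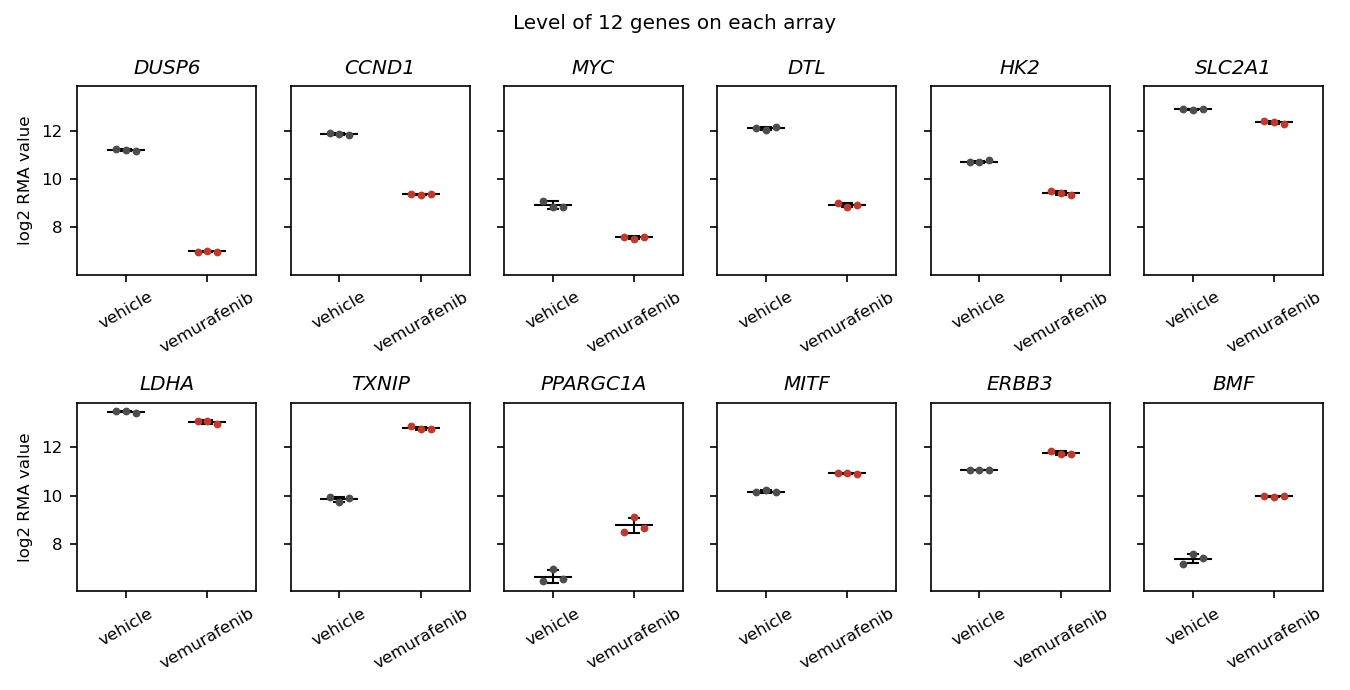
Log2 level (y axis) of 12 genes on each of 3 vehicle and 3 vemurafenib arrays, with points for arrays, a horizontal bar for the mean and whiskers for 1 SD. DUSP6 falls from 11.21 to 7.0 and TXNIP rises from 9.84 to 12.79.

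Of 18 pigment cell differentiation genes, 4 rose and 1 fell (4 and 0 when adjusted over the list alone). MITF, the master transcription factor of pigment cells, rose 1.68-fold from 10.17 ± 0.05 to 10.91 ± 0.03 (SD, n = 3), GPNMB, a melanosomal glycoprotein, 2.56-fold, the melanocortin receptor gene MC1R 1.54-fold and SOX10 1.23-fold. The faller was OCA2 (-0.23), and the list's camera adjusted p was 0.399. MLANA stood at 5.78 in both groups (limma adjusted p 0.9995), near the olfactory receptor median of 5.50. Its level was not shown to be above background, so whether its expression changed cannot be told from these values. Of 13 neural crest and neural adhesion genes, 7 rose and 3 fell, as when adjusted over the list alone, including SEMA6A (4.20-fold higher), FOXD3, a neural crest transcription factor (2.21-fold higher), S100B (1.88-fold higher) and NRCAM (2.08-fold lower). This list passed camera in limma at 0.0276, with adjusted p = 0.447 with an estimated correlation, and did not pass when the array farthest from its group was left out on each side (0.0589, range over the alternatives 0.00989 to 0.0589).

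Of 14 markers of dedifferentiated melanoma, 4 rose and 3 fell, as when adjusted over the list alone. JUN rose 4.74-fold, the stem cell factor SOX2 4.37-fold and TCF4 2.17-fold, and EGFR, the epidermal growth factor receptor, fell 2.38-fold. The list's mean was 0.162, its median -0.081 and its test pointed up, with a limma camera adjusted p of 0.918. Of 23 receptor tyrosine kinases 9 rose and 6 fell (9 and 8 when adjusted over the list alone), with FGFR2 2.19-fold higher, ROR1 3.81-fold lower and EPHA2 2.66-fold lower, while ERBB3, also fixed in advance, was 1.62-fold higher. The mean of that list was -0.008, its median 0.038 and its test pointed up, with a limma camera adjusted p of 0.742. Among 17 YAP and TEAD targets 10 fell and 2 rose (11 and 2 when adjusted over the list alone), with NT5E 7.27-fold, ANKRD1 3.95-fold and CCN1 2.54-fold lower and TGFB2 2.06-fold higher. Their camera adjusted p in limma was 0.00421, with adjusted p = 0.387 with an estimated correlation.

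Among 15 genes of the BCL2 family 6 fell and 4 rose (6 and 5 when adjusted over the list alone), and the limma camera adjusted p was 0.705. BMF, which promotes cell death, rose by 2.58 on the log2 scale, from 7.38 ± 0.20 to 9.97 ± 0.03 (SD, n = 3), and BCL2L11, the gene of the death promoter BIM, by 0.58. PMAIP1, the gene of the death promoter NOXA, fell by 2.20 on the log2 scale, BCL2, a survival gene, fell 1.80-fold and BCL2A1, another survival gene, rose 2.06-fold. Of 20 p53 targets, 10 rose and 4 fell (10 and 5 when adjusted over the list alone), with TP53INP1 4.89-fold and TP53I3 1.98-fold higher and AEN 2.08-fold and PLK3 1.99-fold lower, and a limma camera adjusted p of 0.173. Of 29 lysosome and autophagy genes 18 rose and 1 fell (20 and 1 when adjusted over the list alone). The sialidase NEU1 rose 2.18-fold, the cathepsin CTSF 1.82-fold, the hexosaminidase subunit HEXA 1.75-fold and the peptidase TPP1 1.63-fold, while the galactosidase GLA changed by -0.69. That list passed camera in limma at 0.000205, with adjusted p = 0.387 with an estimated correlation.

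Stress response lists moved downward or in both directions. Of 16 genes of the unfolded protein response 11 fell and 1 rose, likewise when adjusted over the list alone, with the chaperone HSPA5 and the disulfide isomerase PDIA6 each 1.54-fold lower and PDIA4 and XBP1 each 1.44-fold lower; SEL1L was the riser at 0.25. All 12 heat shock genes passed, 10 lower and 2 higher, also when adjusted over the list alone, with HSPH1 2.05-fold, BAG3 1.99-fold and HSPE1 1.85-fold lower. The small heat shock genes CRYAB and HSPB1 were higher, by 2.34 and 0.31 on the log2 scale. Camera gave an adjusted p of 0.00573 in limma for each of the 2 lists, with adjusted p = 0.387 with an estimated correlation. Of 24 genes of the integrated stress response, 9 rose and 6 fell (10 and 6 when adjusted over the list alone), with a limma camera adjusted p of 0.431. The stress-induced NUPR1 rose 8.17-fold and the cystathionine lyase gene CTH 1.77-fold, while MTHFD2, a mitochondrial folate enzyme, fell 2.04-fold and STC2 2.01-fold.

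Of 18 cholesterol synthesis genes, 10 fell and 1 rose (11 and 1 when adjusted over the list alone), with SQLE, DHCR7 and INSIG1 at -0.72, -0.69 and -0.64 and the sterol reductase gene TM7SF2 at 1.37. The list passed camera in limma at 0.0276, with adjusted p = 0.535 with an estimated correlation, and did not pass without vehicle replicate 3 (0.0558) or without the dimmer 50% of genes (0.0718), the range over the alternatives being 0.0103 to 0.0718. Of 13 fatty acid synthesis genes 4 fell and 1 rose, as when adjusted over the list alone. FASN, the fatty acid synthase, stood at -0.61, ELOVL6 at -0.43 and ACACB at 0.94, and the limma camera adjusted p was 0.432. The fall of ELOVL5 (-0.24) was lost without vehicle replicate 3 (limma adjusted p 0.0601) and after renewed quantile normalization (0.0512), the range being 0.000965 to 0.0601.

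Interferon response genes shifted upward, with 13 of 25 higher and 2 lower, likewise when adjusted over the list alone. IFI44L rose 5.04-fold, IFIT2 2.41-fold, IRF9, a subunit of the interferon-activated transcription factor, 2.16-fold and IFI6 1.77-fold, while IRF1 and OAS3 changed by -0.27 and -0.26. Camera in limma gave an adjusted p of 0.000587, and adjusted p = 0.387 with an estimated correlation. Of 12 antigen presentation genes 7 rose and 2 fell, as when adjusted over the list alone, with TAPBP at 0.80, PSMB9 at 0.54, TAP1 at 0.48 and TAP2 at -0.60, and a limma camera adjusted p of 0.179. Of 17 secreted inflammatory factors, 8 fell and 0 rose (9 fell when adjusted over the list alone), with IL24 3.70-fold, LIF 2.65-fold, CXCL8 2.33-fold and CXCL1 2.11-fold lower. That list passed camera in limma at 0.00466, with adjusted p = 0.387 with an estimated correlation.

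Of 21 extracellular matrix and invasion genes, 7 fell and 4 rose, as when adjusted over the list alone, with ITGB3 8.95-fold, the collagenase MMP1 2.86-fold, the urokinase receptor PLAUR 2.16-fold and TNC 1.71-fold lower, and a limma camera adjusted p of 0.178. Markers of another cell type moved alongside: of 7 fibroblast markers 4 rose and 0 fell, likewise when adjusted over the list alone. These were LUM (2.18-fold), PDGFRB (2.12-fold), FAP (log2 change 1.6) and DCN (1.46). The vehicle levels of FAP (5.52) and DCN (5.46) lay at the olfactory receptor median of 5.50, so the sizes of those rises are limited by background. In contrast, COL1A1, COL3A1 and THY1 had log2 changes of 0.01, -0.04 and -0.16 with limma adjusted p values of 0.909, 0.691 and 0.143. After centring THY1 passed at -0.22 (0.0472, range over the alternatives 0.0472 to 0.392). PDGFRB is also among the receptor tyrosine kinases and COL1A1 among the matrix genes. The fibroblast list passed camera in limma at 0.0237, with adjusted p = 0.387 with an estimated correlation, and did not pass without the dimmest 25% of genes (0.307, range over the alternatives 0.00808 to 0.307).

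None of the other lists for other cell types passed camera in limma. Of 6 keratinocyte markers 0 passed the gene test, adjusted over the list alone or not, where KRT14 had a change of 0.27 with a limma adjusted p of 0.0501, and the list's camera adjusted p was 0.918. KRT14 passed in 8 of 17 alternatives, within a limma range of 0.00147 with array weights to 0.192. Among these were the fits without vehicle replicate 2 (0.0129) or vemurafenib replicate 2 (0.0280), so the count of 0 depends on the setting. IVL, at -0.23, passed without vehicle replicate 1 (limma adjusted p 0.0261, range 0.0261 to 0.418), and KRT1, at -0.12, after centring (0.0465, range 0.0465 to 0.461). Of 6 endothelial markers 3 fell and 0 rose, as when adjusted over the list alone, namely KDR (-0.44), PECAM1 (-0.33) and CLDN5 (-0.23), with a list adjusted p of 0.215. The vemurafenib level of PECAM1 (5.42) lay below the olfactory receptor median of 5.50, so the size of its fall is limited by background. The calls of PECAM1 and CLDN5 were each lost without vemurafenib replicate 1 (limma adjusted p 0.0593 and 0.0735) and without vemurafenib replicate 2 (0.0632 and 0.0534), and that of PECAM1 also without vehicle replicate 2 (0.0526). With the mean of its 2 probe sets in place of the brighter, PECAM1 had a change of -0.17 (limma adjusted p 0.133). Over the alternatives these p values ran from 0.00130 to 0.133 for PECAM1 and from 0.00382 to 0.0735 for CLDN5. CDH5, at -0.27 with a limma adjusted p of 0.0695, passed in 6 of 15 alternatives, within a range of 0.0269 to 0.244. These were centring (0.0367), renewed quantile normalization (0.0461), array weights (0.0392), the joint omission of the farthest array of each group (0.0269) and the fits without vehicle replicate 1 (0.0460) or vemurafenib replicate 3 (0.0294). Of 6 leukocyte markers CD68, a lysosomal glycoprotein, rose 2.01-fold while LYZ (-0.75) and CD14 (-0.32) fell, the same calls as when adjusted over the list alone. That list's mean was 0.012, its median -0.017 and its test pointed down, with a limma adjusted p of 0.918. Among 13 common reference genes 5 fell and 2 rose (6 and 2 when adjusted over the list alone), with HPRT1 1.79-fold and TFRC 1.56-fold lower, IPO8 1.37-fold and B2M 1.33-fold higher, and a limma camera adjusted p of 0.469.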

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

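The test of every probe set was planned, and the counts by kind of probe set were taken from it afterwards. These probe sets entered no comparison of the results because no single gene names them. Of the 12083 probe sets with no gene in the platform table, 1949 (16.1%) passed the limma threshold, and 87 were at least 2-fold higher and 70 at least 2-fold lower with vemurafenib. Their extreme log2 changes were 5.63 and -3.10. Of the 1754 probe sets that name several genes, 604 (34.4%) passed, with 28 at least 2-fold higher and 34 at least 2-fold lower, and extremes of 2.05 and -1.79. They drew attention because some of them differed between the groups, in both directions, outside the named genes. No explanation was tested for them.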

How the results depend on the processing

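Only the joint omission of the farthest array of each group (vehicle replicate 2 and vemurafenib replicate 3) was chosen after the data were seen. The count of genes past the limma threshold, 8371 of 18417, was 6190 at a threshold of 0.01. Over the alternatives it ran from 5960 of 9208 genes without the dimmest 50% to 9948 of 33297 when every probe set was tested. The last of these counts probe sets and not genes, and the numbers tested differ, so the counts are not shares of the same whole. The count changed at least 2-fold, 1048, ran from 725 to 1305 in the same 2 settings. The count of lists at the preset correlation, 19, ran from 14 to 20. Leaving out each array in turn gave 7218 to 8326 genes, 1044 to 1083 genes changed at least 2-fold and 17 to 19 lists. The joint omission gave 8417 genes, 1051 genes and 16 lists. In each alternative, 0 genes called both there and in the planned design changed direction. Camera with an estimated correlation passed 0 lists, with 3 at an unadjusted p under 0.05, against 27 by fry. The estimated correlations within lists exceeded the preset 0.01 in most lists, for example 0.516 for DNA replication and 0.755 for mitosis. Their size does not account for all of the loss. Lysosome and autophagy, estimated at 0.03, went from an unadjusted limma camera p of 3.42e-05 to 0.0262. Regulators of glycolysis, estimated at -0.044 and so under the preset, went from 0.042 to 0.101. Of list means over the alternatives at the preset correlation, 511 stayed on their side of the threshold, 20 lost and 1 gained a call. Of named genes 2959 stayed, 15 lost and 17 gained one. The estimated correlation and fry are left out of this tally and of the ranges over alternatives given for lists. By level, limma called 21.5% of the dimmest 25% of genes, 41.8% and 59.6% of the next 2 groups of that size and 58.9% of the brightest; whether background hid changes of dim genes was not tested.

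The groups share replicate numbers, and the design text speaks of paired dishes by letter, but the labels tie a letter to a number for only 1 array. Deviations from the group means correlated at 0.142, -0.184 and -0.251 between same-numbered arrays, and only the replicate 1 arrays correlated best with their own number (vehicle 2 with vemurafenib 3 reached 0.279 and vehicle 3 with vemurafenib 2 reached 0.225). The numbers were therefore not taken to pair the arrays, and a block by number leaves the lettered pairing untested. Together the highest correlations (0.142, 0.279 and 0.225) would place each array in a single pair, but no fit used that pairing. With the replicate block as a fixed term, limma called 7606 genes (7519 of them shared with the fit without it), 1048 genes changed at least 2-fold and 19 lists, and as a random effect 7923, 1048 and 19. Among named genes and lists the fixed block changed the call of RPS24 alone.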

Other observations

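The tests of the gene groups described first, of the collagens and of S phase against mitosis were chosen after results were seen, while the other tests were set out before theirs. Members of the histone, recombination repair, semaphorin and protocadherin groups had already appeared among the largest changes, so their direction is not independent evidence. Of 42 genes of the protocadherin family of neural cell adhesion molecules, the pseudogenes PCDHB17P and PCDHB18P among them, 38 rose and 1 fell, with PCDH20, PCDH10 and PCDH7 at 2.62, 2.06 and 2.06. The limma camera adjusted p over 12 such groups was 3.39e-15, with adjusted p = 0.0859 with an estimated correlation. Of 28 semaphorins and plexins, guidance cues and their receptors, 14 rose and 5 fell, with SEMA3C at 2.34 (limma adjusted p 0.0113, adjusted p = 0.306 with an estimated correlation). Of 16 circadian clock genes 7 rose and 1 fell, with BHLHE41 at 1.53 and DBP at 0.91 (limma adjusted p 0.0392, adjusted p = 0.260 with an estimated correlation).

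Of 56 replication-dependent histone genes, 49 fell and 1 rose, counting H4C14 and H4C15, whose values were identical on every array, as 2 genes, with H1-5 at -2.18 and H2BC3 at -2.13 (limma adjusted p 1.73e-19, adjusted p = 0.0918 with an estimated correlation). Histone and clustered protocadherin genes resemble each other in sequence, and their probe sets are uncertain as measures of single genes. Of 25 genes of homologous recombination and crosslink repair 23 fell and 1 rose, with EXO1 at -2.60, XRCC2 at -2.51 and BLM at -2.32 (limma adjusted p 6.34e-12, adjusted p = 0.260 with an estimated correlation). Of 20 nucleoporins 16 fell and 1 rose (limma adjusted p 2.63e-07, adjusted p = 0.332 with an estimated correlation). Of 36 proteasome subunits 21 fell and 3 rose, the risers being the interferon-inducible PSMB9 (0.54), PSMB8 (0.42) and PSMB10 (0.25), and of 70 mitochondrial ribosomal proteins 31 fell and 4 rose. These lists had limma adjusted p values of 0.00103 and 0.000230, each with adjusted p = 0.415 with an estimated correlation. Of 19 cytosolic tRNA synthetases 11 fell and 2 rose (limma adjusted p 0.0164, adjusted p = 0.447 with an estimated correlation), and of 439 numbered zinc finger genes 142 rose and 65 fell (limma adjusted p 0.0113, adjusted p = 0.637 with an estimated correlation). Of 14 NRF2 targets 3 rose, among them HMOX1 at 1.23, and 6 fell, with a limma adjusted p of 0.371.

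Nearly 50% of genes passed the threshold. The arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The labelled split called 8371 genes, 1048 genes changed at least 2-fold and 19 lists, against at most 0, 0 and 13 in other splits, and only 1 of the 10, the labelled one, reached each of these values. Every other split mixed drug and vehicle arrays in both groups, so a drug effect would widen their spread and keep gene calls low. Such splits also retain part of the drug contrast. The comparison therefore cannot show what counts would arise without a drug effect. Whether background probe sets were called along with expressed genes was tested on 341 olfactory receptor genes, whose median level was 5.50 against 8.37 over all genes. Of them, 19 rose and 31 fell, so 50 passed (14.66%, exact 95% interval 11.08 to 18.87). This lay between the bounds set beforehand, under 10% against such calls and at least 50% of the overall 45.5% for them. Genes that melanoma cells hardly express were thus among those called, less often than all genes. The adjusted threshold lay near an unadjusted limma p of 0.023, so their share was above that expected of unchanged, independent genes. Their estimated correlation was 0.125, and the exact interval ignores it. How much background probe sets add to the count stays open.

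Oxidative phosphorylation and ribosomal protein genes leaned upward by small amounts, with medians of 0.137 and 0.114, and stood at adjusted p = 0.666 and adjusted p = 0.535 with an estimated correlation in limma. If bright probe sets had risen in general, random sets of the same mean level would lie as high, but the medians stood at percentiles 99.55 and 99.23 of 10000 such sets. This argues against a general rise of bright probe sets, although the sets ignore correlation between genes. Centring ended both calls (limma adjusted p 0.0534 and 0.0718, ranges over the alternatives 0.00635 to 0.170 and 0.00581 to 0.101), but it moved all genes alike, their median going from -0.045 to -0.106, and so does not set these lists apart from other genes. Their difference between drug and vehicle thus passed some tests and not others, with fry adjusted p values in limma of 0.0682 and 0.00841.

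LUM, DCN, FAP and PDGFRB, markers of fibroblasts, rose in a culture of a melanoma line. Fibroblasts mixed into the treated dishes would bring their abundant collagen RNA, and the highest upper 95% bound of change among COL1A1, COL1A2 and COL3A1 was 0.185, below the lowest lower bound of LUM and DCN, 0.882. The collagens already had vehicle levels of 8.41, 7.29 and 7.22, above the olfactory receptor median of 5.50, and such a baseline could hide the collagen of a small share of fibroblasts. LUM, however, rose by 1.13 from a vehicle level of 8.58, above those of all 3 collagens. PDGFRB rose by 1.08 (lower 95% bound 0.885) from a vehicle level of 8.18, above those of COL1A2 and COL3A1. Fibroblasts enough for those rises would have lifted the collagens too, as far as levels of different probe sets can be compared. The values thus argue against admixed fibroblasts as the source of the rises of LUM and PDGFRB. For DCN and FAP, whose vehicle levels lay at the olfactory receptor median, admixed fibroblasts stay open. The hypothesis that the melanoma cells express LUM, DCN, FAP and PDGFRB also stays open, and in situ hybridization on treated cultures would test it.

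S phase genes fell further than mitotic genes, with a difference of list means of -0.514 (SD 0.042 over vehicle arrays and 0.115 over vemurafenib arrays). The exact 2-sided permutation p over arrays was 0.1, the smallest that 3 against 3 arrays allow. A permutation of genes between the lists gave 1e-04, the smallest its 10000 draws can give, with genes that are not independent. No explanation of this difference was tested.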
